A study of Mus musculus with 6 samples.

How the data were processed

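Total RNA of mouse liver was measured in 6 samples, 3 labelled control and 3 labelled heparin. Per the labels' protocols, RNA was extracted with TRIzol, 1 µg per sample was enriched for mRNA on oligo(dT) beads, and paired reads of 150 bp were taken on a NovaSeq instrument. The submitters' processing notes name fastp, HISAT2, SAMtools, featureCounts, Subread and the mouse build GRCm39. Versions, strand settings and the gene annotation are not given in the sources used here.

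The deposited table holds raw counts per gene, whole numbers that the authors did not normalize, for 49671 Ensembl gene IDs in 6 sample columns. Symbols were matched by ID from a reference list of gene names, which gave them for 49326 IDs (99.3%), and biotypes were matched by ID to GENCODE mouse release 21. In all, 23178 IDs had a count in some library, and no row named something other than a gene. The 6124 IDs of that GENCODE release that the table lacks are all numbered above its highest ID, so the counting annotation looks older than the release, and no coordinates are given. Among genes with 1 to 12 counts, even counts made up 61.1 to 67.0% in the 6 libraries, and 2 counts were more frequent than 1 in each. A count is therefore treated as a read end, not as a molecule, and intervals and floors, which cover counting error only, are narrower than the number of molecules would give. Without strand information, genes overlapping on opposite strands cannot be told apart, and members of gene families can share reads.

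Totals ran from 24727970 to 32396416 counts, a ratio of 1.31. Genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Low genes were removed with filterByExpr by group, which left 13943, and libraries were scaled by TMM. The TMM factors were 1.148, 1.204 and 1.132 for the control libraries and 0.844, 0.866 and 0.874 for the heparin libraries. The quasi-likelihood test (glmQLFit with robust dispersion, glmQLFTest) compared heparin with control in a model of group alone, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are heparin over control on the log2 scale, with the Wald standard error of the fit, and CPM are counts per 1000000 of the TMM-scaled total. For a gene at 0 in a group the bound sets 3 counts over that group. Principal components used log2 CPM with a prior count of 2. Within groups the correlation of log2 CPM was 0.978 to 0.988, and chi-square per degree of freedom between replicates was at least 11.4, so no library repeated another.

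Before the data were examined, 41 gene lists of liver biology, cell types, sex bias and RNA quality were written down, together with the comparisons and the rule for named genes. Named are Hrg, Fgfr1, Fgfr2, Fgfr3, Fgfr4, Klb and Mapk3. So are the 12 genes with the largest rise and the 12 with the largest fall at an adjusted p under 0.05, a mean of at least 2 CPM and groups that do not overlap, leaving out symbols that are only clone or predicted-gene numbers. From each list up to 4 tested members with the smallest p could be named. Some genes that the rule takes are not reported here. Members of each list were counted as risen, fallen or not called, over all genes and adjusted over the list alone. The 39 lists with at least 5 tested members were tested against other genes with camera in limma 3.58.1 at a preset correlation of 0.01, two-sided, with adjustment over the lists, beside camera with an estimated correlation and fry, which tests a list without other genes. Called with the preset value were 10 lists, and 4 of these held with an estimated correlation.

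Alternatives were size factors by relative log expression, library totals alone, DESeq2 1.42.0, limma-voom, no low-count filter, a mean count of at least 10, non-robust dispersion, a replicate block, the 20 most abundant genes left out, a threshold of 0.1 and each library left out in turn. The procedure was tested on simulated counts for the real genes and library sizes. Of 13943 genes simulated for heparin against control, 13469 passed the filter, and 51.0% of 100 genes changed 1.5-fold and 75.0% of 100 changed 2-fold were called. In that simulation 8 calls were false (5.97%), and among 38 lists both that had been shifted were called and none of the others. Simulated genes varied independently and few were changed. The simulation therefore does not cover correlated lists or a change as wide as the 59.2% of genes called in the real data. Checks and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.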

Results

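Liver RNA from mice labelled control and mice labelled heparin was compared by sequencing of poly(A) mRNA. Heparin is a sulfated polysaccharide used as an anticoagulant. The series title places these livers in work on heparin-induced thrombocytopenia, a reaction to heparin in which platelets fall and clots form, and it names the FGF receptors, the kinase ERK and the plasma protein HRG. There were 3 libraries per group. The control libraries held 24727970, 28217139 and 29046126 counts and the heparin libraries 32116197, 32396416 and 30899373. The labels give no dose, time after heparin, strain or sex, and they do not say that replicates came from separate animals, so p-values measure only the spread between these libraries.

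The heparin livers carried much more acute phase and inflammatory mRNA than the control livers. All 23 acute phase genes measured rose, among them Lcn2 (lipocalin 2, an iron-binding defence protein) from 18.5 ± 3.48 to 6982 ± 329 counts per 1000000 (CPM; mean ± SD, n = 3). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 83.2 ± 14.2 to 0.488 ± 0.091 CPM, and G6pc, the catalytic subunit of glucose-6-phosphatase, from 474 ± 24.5 to 5.07 ± 0.633 CPM. Hrg fell from 718 ± 5.0 to 453 ± 16.6 CPM, and the hepatocyte FGF receptor Fgfr4 from 54.5 ± 0.32 to 18.2 ± 0.692 CPM.

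Of 13943 genes tested, 8250 (59.2%) changed at an adjusted p under 0.05, 4160 upward and 4090 downward. Changes of 4-fold or more were found in 684 genes that rose and 762 that fell. The groups did not overlap in 65.4% of the genes tested, against 10% by chance for 3 libraries against 3. The first principal component held 81.8% of the variance and separated the groups. The second, with 6.90%, set heparin replicate 1 (-42.6) apart from heparin replicates 2 and 3 (14.9 and 27.0). Directions are relative to the bulk of genes, which TMM scaling centres. With library totals alone the median gene moved by -0.44 on the log2 scale, and 2183 genes were called higher and 6861 lower.

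The largest rises were taken among genes averaging at least 2 CPM whose groups did not overlap. Saa3 (serum amyloid A3) rose from 2.41 ± 0.662 to 3672 ± 597 CPM. Cdkn1a, the cell cycle inhibitor p21, rose from 0.868 ± 0.421 to 356 ± 7.44 CPM. Serpina3f (log2 fold change 9.42 ± 0.382 SE) and the adenylyl cyclase Adcy1 (8.90 ± 0.434) rose too. Tm4sf20 rose to 32.7 ± 7.71 CPM, but its 6 control counts all lay in control replicate 1, and the other control libraries were at 0. Slc10a6, a transporter of sulfated steroids, had no count in the control libraries and was at least 878-fold higher with heparin, taking 3 counts over the control group as the floor. On the same floor Tub was at least 685-fold higher, the antimicrobial lectins Reg3b and Reg3g at least 478-fold and 368-fold higher, and Csf3, which encodes the neutrophil growth factor G-CSF, at least 156-fold higher. A2m, the protease inhibitor alpha-2-macroglobulin, had 2 control counts, and its ratio was 788 (95% exact counting interval 218 to 6510). The adjusted p of these genes ran from 1.06e-14 for Serpina3f to 4.32e-06 for Tm4sf20. Serpina3f, Reg3b and Reg3g have close paralogs with which reads can be shared.

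The largest falls by the same rule included Cyp7a1 (log2 fold change -7.40 ± 0.256 SE, adjusted p = 1.11e-13) and G6pc (-6.55 ± 0.0949, adjusted p = 1.73e-15). G0s2, an inhibitor of triglyceride lipase, fell from 133 ± 32.1 to 1.35 ± 0.692 CPM. Nr0b2, the nuclear receptor SHP, fell from 81.2 ± 5.46 to 1.89 ± 0.0649 CPM, and Hsd3b5, a steroid dehydrogenase high in male mouse liver, by 5.02 ± 0.0829 on the log2 scale. Angptl8, a secreted regulator of lipoprotein lipase, fell from 79.2 ± 14.5 to 2.70 ± 0.362 CPM. Hfe2, which encodes the BMP co-receptor hemojuvelin, fell from 85.8 ± 6.32 to 3.09 ± 0.968 CPM. The remaining members were Gprin3 (-6.68 ± 0.429), the orphan receptor Gpr12 (-5.68 ± 0.668), Fam89a (-5.29 ± 0.278), Tmie (-5.19 ± 0.39) and Spsb4 (-4.65 ± 0.299).

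Hrg (ENSMUSG00000022877), which encodes the heparin-binding plasma protein histidine-rich glycoprotein, was the gene named by the series title. It fell by 0.66 ± 0.066 (SE) on the log2 scale with an adjusted p of 4.95e-07, and all 3 heparin libraries (437 to 470 CPM) lay below all 3 control libraries (713 to 723 CPM). With library totals alone the log2 fold change was -1.10. An exact two-sided permutation test of the log2 CPM gave p = 0.1, the smallest that 3 libraries against 3 can give. The fall of Hrg was one among several plasma protein genes that moved in both directions.

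The FGF receptor genes did not move together. Fgfr4 fell by 1.58 ± 0.0864 on the log2 scale (adjusted p = 5.23e-10) and Klb, its co-receptor beta-Klotho, by 2.48 ± 0.184 (1.88e-08), from 14.4 ± 2.38 to 2.58 ± 0.406 CPM. Fgfr3 fell by 1.30 ± 0.14 (1.39e-06). Fgfr1 rose from 2.01 ± 0.282 to 4.38 ± 0.898 CPM, and Fgfr2 rose by 0.67 ± 0.146, a call that library totals ended (0.23, adjusted p = 0.155, against 4.59e-11 to 0.155 over its alternatives). Mapk3, which encodes ERK1, fell by 0.83 ± 0.11 (1.11e-05). Grb2, an adaptor of receptor signalling, rose from 43.2 ± 1.37 to 87.7 ± 2.14 CPM.

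**Figure D1:**
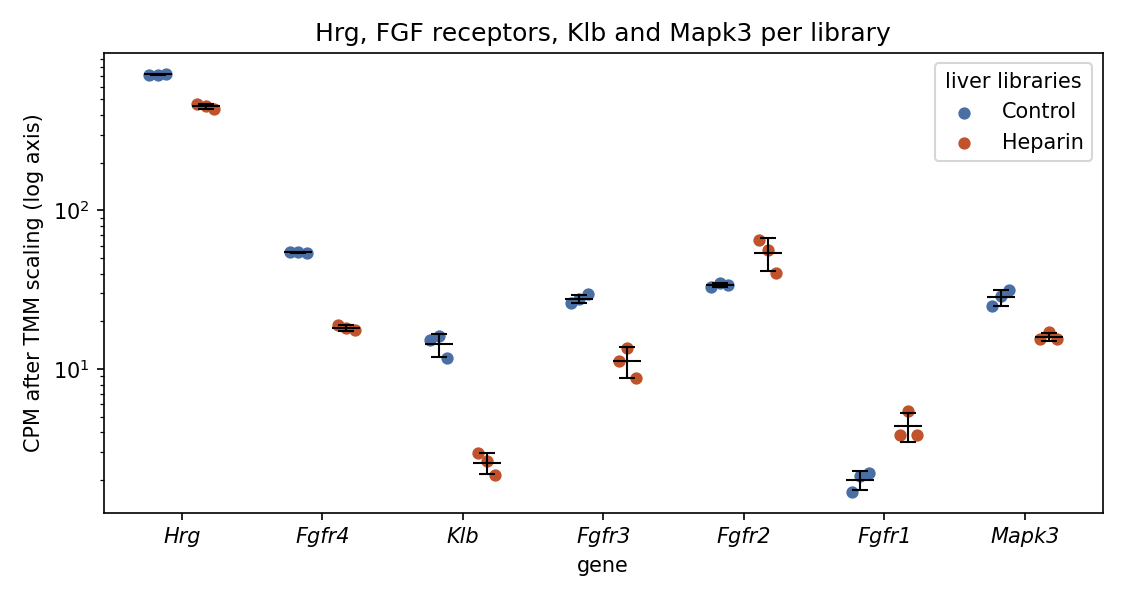
CPM after TMM scaling (log axis) of Hrg, Fgfr4, Klb, Fgfr3, Fgfr2, Fgfr1 and Mapk3 in each liver library; points are the 3 libraries per group, horizontal bars the means and whiskers ± 1 SD. Control and heparin points do not overlap for any of these genes.

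In the list of FGF receptors and ERK cascade genes, 12 of 24 rose, 7 fell and 5 were not called, the same counts when adjusted over the list alone, whereas with library totals 4 rose and 11 fell. The list as a whole was not called against other genes (camera adjusted p = 0.873). Genes transcribed in response to ERK were mixed: 9 of 16 rose and 2 fell (9 and 3 adjusted over the list alone), or 6 and 5 with library totals and 7 and 4 without heparin replicate 3, with no call for the list (adjusted p = 0.173). Ier3 rose from 0.452 ± 0.179 to 74.7 ± 3.44 CPM and Egr1 from 9.34 ± 1.5 to 36.9 ± 4.99 CPM. Dusp6, the phosphatase that switches ERK off, fell from 32.3 ± 4.86 to 8.42 ± 0.85 CPM, and Phlda1 from 48.1 ± 3.68 to 16.3 ± 0.733 CPM.

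All 23 acute phase genes tested rose, also when adjusted over the list alone, with a median log2 fold change of 3.29 and a camera adjusted p of 2.59e-49 (adjusted p = 0.0476 with an estimated correlation). Serpina3n, a protease inhibitor, rose from 820 ± 41.8 to 18760 ± 1450 CPM, and Steap4, a metalloreductase, from 154 ± 8.55 to 13420 ± 1150 CPM. Socs3, the feedback inhibitor of IL-6 signalling, rose from 10.3 ± 0.481 to 340 ± 14.8 CPM. These 23 genes took 1.86 to 2.03% of the counts in control libraries and 10.2 to 11.5% in heparin libraries. Reads can be shared within the Saa, Orm and Serpina3 families.

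Inflammatory cytokines and NF-kB targets rose in 12 of the 13 cases tested, with none lower, on either adjustment (adjusted over the list alone, 12 and 0). Tnf, Il6, Ccl3, Ccl4, Sele and Ptgs2 had too few counts to be tested, and Il6 had none in any library. The list median was 3.17 and the camera adjusted p 1.79e-14 (adjusted p = 0.0414 with an estimated correlation). The chemokine gene Cxcl9 rose from 2.73 ± 0.117 to 80.0 ± 11.8 CPM, the adhesion molecule Icam1 from 7.53 ± 0.97 to 126 ± 14.1 CPM, the NF-kB inhibitor Nfkbia from 27.2 ± 0.847 to 153 ± 3.81 CPM and Relb from 1.05 ± 0.241 to 20.3 ± 0.557 CPM. Immediate early genes rose in 12 of 15 cases and fell in 2, also when adjusted over the list alone (camera adjusted p = 3.81e-15; adjusted p = 0.0291 with an estimated correlation). Junb rose from 16.2 ± 1.19 to 221 ± 7.94 CPM, Jun by 3.42 ± 0.095 on the log2 scale and Klf6 from 3.83 ± 0.318 to 99.0 ± 10.3 CPM. Interferon-response genes rose in 12 of 23 cases and fell in 3 (13 and 3 adjusted over the list alone), or 8 and 5 with library totals, and the list was not called (adjusted p = 0.0706). Leaving out control replicate 1 or 3, or heparin replicate 2, brought its adjusted p to 0.0469, 0.0376 and 0.0445, limma-voom to 0.0255 and no low-count filter to 0.00493, and over all camera alternatives it ran from 0.00493 to 0.901. Gbp2 rose by 3.94 ± 0.227 and Usp18 by 1.85 ± 0.124.

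The stress lists differed. Of 17 genes of ER stress and the integrated stress response, 16 rose and none fell (16 and 1 adjusted over the list alone), with a median of 1.66 and a camera adjusted p of 6.39e-12 (adjusted p = 0.0291 with an estimated correlation). Dnajb9, an ER chaperone cofactor, rose by 2.75 ± 0.0833 on the log2 scale, Herpud1 from 261 ± 14.6 to 1063 ± 64.0 CPM and Hyou1 from 112 ± 3.29 to 356 ± 42.8 CPM. Targets of p53 rose in 8 of 13 cases and fell in 4, also when adjusted over the list alone (camera adjusted p = 8.31e-08; adjusted p = 0.11 with an estimated correlation), and limma-voom gave 0.0512, against 3.35e-12 to 0.11 over its alternatives. Gdf15, a stress-induced hormone, rose from 2.96 ± 0.373 to 80.8 ± 9.85 CPM, Btg2 from 3.21 ± 0.482 to 196 ± 25.0 CPM and Trp53inp1 from 45.6 ± 6.49 to 510 ± 88.7 CPM. Heat shock genes went both ways, with 5 of 12 higher and 3 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.813), and 2 higher and 7 lower with library totals. Bag3 rose from 13.8 ± 0.845 to 97.5 ± 3.93 CPM and Hspb1 fell from 35.5 ± 6.79 to 6.56 ± 1.36 CPM. NRF2 targets were also split, with 4 of 13 higher and 5 lower on either adjustment (adjusted over the list alone, 4 and 5; camera adjusted p = 0.768), or 3 and 7 with library totals. Txnrd1 rose by 1.23 ± 0.0746 while the glutathione synthesis genes Gclc and Gclm fell by 1.28 ± 0.0811 and by 0.84 ± 0.071.

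**Figure D2:**
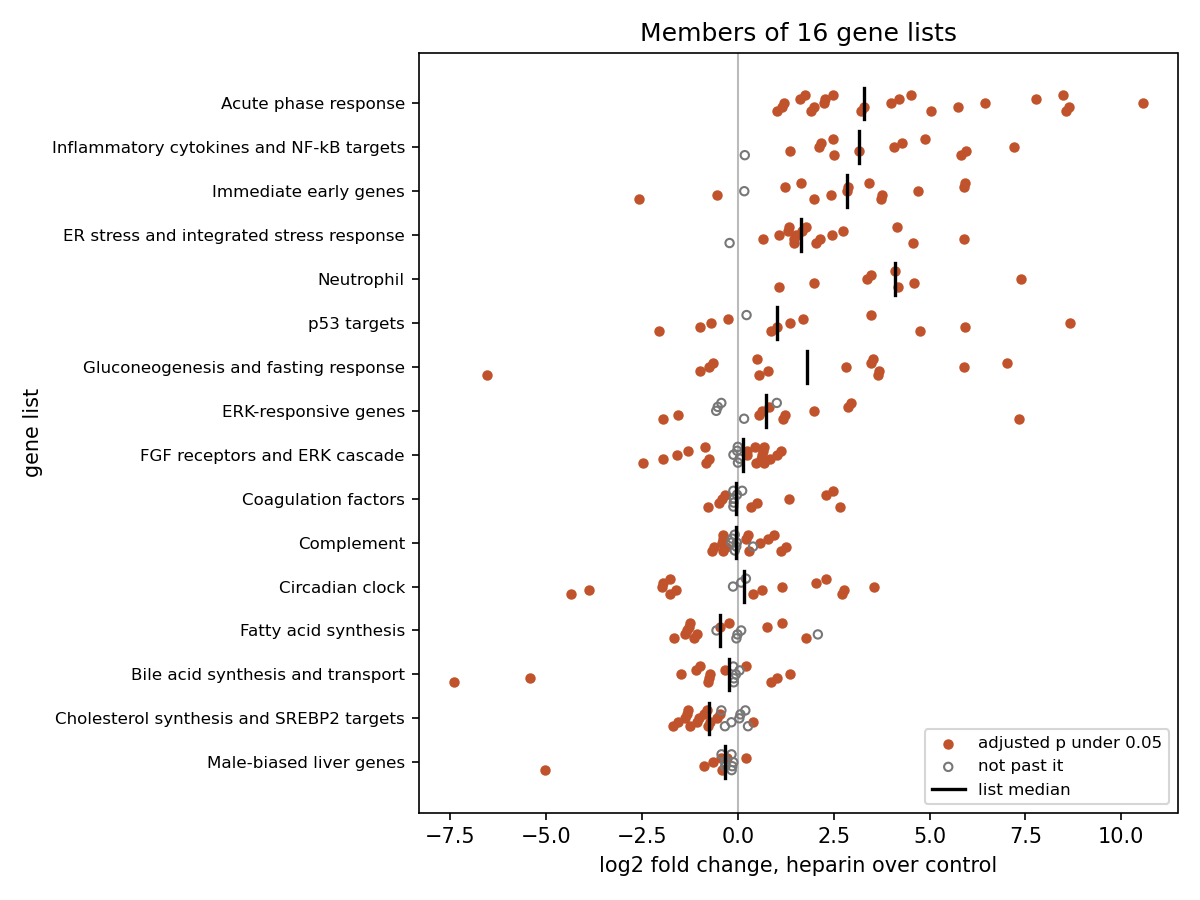
Log2 fold change (heparin over control, after TMM scaling) of the tested members of 16 gene lists; each point is a gene, filled where the edgeR adjusted p is under 0.05, and the vertical bars are list medians. Ngp, with no control count, is left out of the neutrophil points. All acute phase members lie to the right of 0, and 14 of the 22 cholesterol synthesis members are called to the left, while with library totals more FGF receptor and ERK cascade, coagulation, complement and clock genes fell than rose.

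Bile acid genes were lower as a list, with 9 of 18 down and 4 up, also when adjusted over the list alone, and 14 down and 3 up with library totals (camera adjusted p = 0.00152; adjusted p = 0.11 with an estimated correlation). Limma-voom ended this call (adjusted p = 0.0674, against 3.91e-05 to 0.11 over its alternatives). Cyp8b1, the sterol 12-alpha-hydroxylase, fell from 371 ± 33.3 to 133 ± 7.32 CPM, beside Cyp7a1 and Nr0b2, while Cyp2c70, which makes muricholic acids, rose from 797 ± 85.9 to 2057 ± 67.0 CPM. Cholesterol synthesis and other SREBP2 targets fell in 14 of 22 cases and rose in 1, on either adjustment (adjusted over the list alone, 14 and 1), and 18 fell and 0 rose with library totals, with a camera adjusted p of 0.00647 (adjusted p = 0.961 with an estimated correlation). Fdft1, squalene synthase, fell by 1.69 ± 0.115 and Sc5d by 1.55 ± 0.116 on the log2 scale, Hmgcs1 from 252 ± 37.5 to 107 ± 10.4 CPM and Mvk from 21.8 ± 1.22 to 8.78 ± 0.434 CPM.

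Fatty acid synthesis genes fell in 9 of 17 cases and rose in 3 (10 and 4 adjusted over the list alone), or 13 and 2 with library totals, without a call for the list (adjusted p = 0.241). The lipogenic regulators Srebf1 and Mlxipl fell by 1.67 ± 0.0931 and by 1.15 ± 0.0779, whereas Thrsp rose by 1.77 ± 0.0746. Fatty acid oxidation genes and PPARA targets rose in 10 of 22 cases and fell in 6 (10 and 8 adjusted over the list alone; camera adjusted p = 0.606), and 7 rose and 11 fell with library totals. Without heparin replicate 1 that list's adjusted p was 0.0462, the lowest of its camera alternatives, which ran up to 0.976. The fatty acid transporter Cd36 rose by 2.86 ± 0.219 and the peroxisomal thiolase Acaa1b fell by 0.98 ± 0.0728 on the log2 scale. In the gluconeogenesis and fasting list 10 of 14 genes rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 1.05e-06; adjusted p = 0.524 with an estimated correlation). Those that rose included the amino acid catabolism genes Tat, from 711 ± 25.1 to 8960 ± 609 CPM, and Sds, from 49.2 ± 3.95 to 351 ± 17.8 CPM, and the stress gene Gadd45b (5.89 ± 0.196). G6pc and Pck1, the enzymes that release glucose and start gluconeogenesis, fell by 6.55 ± 0.0949 and by 0.65 ± 0.0757.

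Coagulation factor genes rose in 6 of 16 cases and fell in 4, also when adjusted over the list alone (camera adjusted p = 0.227), but with library totals 3 rose and 9 fell. Without the 20 most abundant genes 3 rose and 4 fell. That setting takes abundant list members out of the data, so its fewer rises follow from its construction. The fibrinogen chains rose together: Fga from 4596 ± 124 to 29360 ± 2600 CPM, Fgb from 4558 ± 183 to 22550 ± 1470 CPM and Fgg from 3296 ± 87.1 to 18520 ± 1060 CPM. Klkb1, plasma prekallikrein, fell from 180 ± 9.66 to 105 ± 4.89 CPM. Anticoagulant and fibrinolytic plasma proteins rose in 8 of 18 cases and fell in 7 (9 and 7 adjusted over the list alone; camera adjusted p = 0.109), but with library totals 6 rose and 9 fell. Their adjusted p was 0.0261 without heparin replicate 1, 0.0399 without heparin replicate 2 and 0.0137 with no low-count filter, against 0.0137 to 0.71 over the list's camera alternatives. Serpina10, the protein Z-dependent protease inhibitor, rose from 289 ± 14.9 to 1388 ± 57.0 CPM, and Cpb2, which encodes the fibrinolysis inhibitor TAFI, from 367 ± 13.9 to 868 ± 17.5 CPM. Complement genes rose in 8 of 22 cases and fell in 7 (9 and 7 adjusted over the list alone; camera adjusted p = 0.928), but with library totals 3 rose and 14 fell, and without control replicate 3 or heparin replicate 1 there were 6 up and 7 down. C3 rose from 5349 ± 164 to 11610 ± 686 CPM, and Hc, which encodes C5, fell from 1015 ± 37.1 to 658 ± 39.4 CPM.

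Iron and BMP-SMAD genes rose in 8 of 17 cases and fell in 3 (10 and 4 adjusted over the list alone; camera adjusted p = 0.873), with 5 up and 6 down on library totals. Hfe rose from 27.2 ± 2.06 to 135 ± 12.1 CPM, and the iron exporter ferroportin, Slc40a1, fell from 147 ± 17.3 to 21.4 ± 2.57 CPM, beside the fall of Hfe2. Genes of heparan sulfate synthesis and proteoglycans rose in 7 of 23 cases and fell in 8, on either adjustment (adjusted over the list alone, 7 and 8; camera adjusted p = 0.768), with 6 up and 12 down on library totals and 7 up and 6 down without control replicate 1. Ext1, a chain polymerase, and Extl3, a glycosyltransferase that acts at the start of the chain, rose by 1.18 ± 0.0881 and by 1.45 ± 0.0971, and the syndecans Sdc1 and Sdc4 by 0.96 ± 0.0741 and by 0.89 ± 0.0788. Xenobiotic metabolism genes rose in 3 of 19 cases and fell in 5, also when adjusted over the list alone (camera adjusted p = 0.823), with 1 up and 13 down on library totals. Without heparin replicate 1 the balance turned to 5 up and 3 down, and without control replicate 3 or heparin replicate 2 it was 2 up and 3 down. Cyp2b10 rose by 4.87 ± 0.347 and Cyp3a25 fell by 0.67 ± 0.0692 on the log2 scale. Circadian clock genes rose in 8 of 18 cases and fell in 7, also when adjusted over the list alone (camera adjusted p = 0.606), with 6 up and 9 down on library totals. Nfil3 rose from 32.6 ± 2.91 to 135 ± 8.3 CPM, while Dbp fell from 20.8 ± 4.11 to 1.02 ± 0.302 CPM and Per3 from 25.6 ± 3.57 to 1.74 ± 0.458 CPM. Cell cycle genes rose in none of 15 cases and fell in 4 on either adjustment (adjusted over the list alone, 0 and 4; camera adjusted p = 0.606), or 0 and 7 with library totals, with Mcm2 going from 5.29 ± 1.22 to 1.68 ± 0.469 CPM.

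Hepatocyte markers kept a median near 0 (-0.01), with 6 of 18 higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.606), and 3 higher and 11 lower with library totals. Tdo2 rose from 1015 ± 31.2 to 2721 ± 140 CPM and the transcription factor Hnf4a from 389 ± 33.0 to 1002 ± 84.7 CPM. Pericentral markers were split, 4 up and 5 down of 13, also when adjusted over the list alone (camera adjusted p = 0.976), or 3 and 7 with library totals. Glutamine synthetase, Glul, rose from 464 ± 20.4 to 1609 ± 242 CPM, while the Wnt-responsive genes Tbx3 and Lgr5 fell by 1.73 ± 0.151 and by 3.25 ± 0.37. Periportal markers were also split, 5 up and 5 down of 12 (5 and 6 adjusted over the list alone; camera adjusted p = 0.928), or 2 up and 7 down with library totals, with Hal falling from 181 ± 12.6 to 74.9 ± 9.02 CPM. Male-biased liver genes fell in 6 of 14 cases and rose in 1, on either adjustment (adjusted over the list alone, 6 and 1), and 11 fell and 0 rose with library totals, with a camera adjusted p of 0.0171 (adjusted p = 0.703 with an estimated correlation). Beside Hsd3b5, Mup20 fell by 0.65 ± 0.107 and Selenbp2 by 0.43 ± 0.0821, and reads can be shared among the Mup genes. Female-biased genes rose in 3 of 7 cases and fell in 1, also when adjusted over the list alone (camera adjusted p = 0.823). The member with the smallest p, Acot3, fell by 2.02 ± 0.287, and Cyp17a1 rose by 1.29 ± 0.186. A1bg and Cux2, which also rose, had only 4 and 18 control counts. The remaining members of the 14 listed had too few counts to be tested.

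All 9 neutrophil marker genes tested rose, also when adjusted over the list alone, with a median of 4.10 that was the same with Ngp at its bound (camera adjusted p = 0.00647; adjusted p = 0.703 with an estimated correlation). S100a9 rose from 1.12 ± 0.28 to 12.6 ± 4.26 CPM and S100a8 from 0.355 ± 0.162 to 6.39 ± 2.75 CPM. Mmp8 had 2 control counts and a ratio of 199 (95% exact counting interval 54.6 to 1650), and Ngp had none and was at least 94.6-fold higher. S100a8, Mmp8 and Ngp passed the low-count filter only through the heparin libraries, while S100a9 had 107 control counts. The other listed markers, Ly6g, Elane, Mpo and Camp, had too few counts to be tested. Ly6g had 2, 0 and 5 control and 2, 2 and 4 heparin counts, and Elane 2, 6 and 0 and 0, 2 and 0. Mpo had none, and Camp had 0 in each control library and 2, 17 and 19 with heparin. Of 7 B cell markers 4 fell and none rose, also when adjusted over the list alone (median -2.18, the same with genes at 0 in a group at their bound; camera adjusted p = 0.318). Cd79b, with 1 heparin count, had a ratio of 0.0176 (95% exact counting interval 0.000438 to 0.101), and Bank1 fell from 1.01 ± 0.173 to 0.219 ± 0.222 CPM, a call that ended without control replicate 3 (log2 fold change -2.12, adjusted p = 0.0528, against 0.00129 to 0.0528 over its alternatives).

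Kupffer cell and macrophage markers rose in 1 of 13 cases and fell in 1 (1 and 0 adjusted over the list alone; camera adjusted p = 0.879). Marco, a scavenger receptor, rose from 0.515 ± 0.145 to 8.65 ± 3.3 CPM. Without heparin replicate 3, and with limma-voom, 1 rose and 5 fell. The call of Timd4 (-0.88) ended without control replicate 1, 2 or 3 or heparin replicate 1 or 2 (adjusted p of 0.0585 to 0.117, against 0.00365 to 0.117 over its alternatives). Its log2 fold change was then -0.82, -0.90 and -0.93 for the control replicates and -0.58 and -0.93 for the heparin replicates. Sinusoidal endothelial markers rose in 1 of 16 cases and fell in 1 (0 and 1 adjusted over the list alone; camera adjusted p = 0.809). The VEGF receptor gene Kdr fell from 12.9 ± 1.47 to 2.52 ± 0.999 CPM. Lyve1 was called higher (4.36 ± 0.953 on the log2 scale, adjusted p = 0.0164). Without control replicate 1, 2 or 3 its adjusted p was 0.0672, 0.0635 and 0.0681, while the log2 fold change stayed at 4.16, 4.58 and 4.36. Over its alternatives the adjusted p ran from 1.06e-10, without heparin replicate 1, to 0.0681. Stellate cell and fibroblast markers fell in 7 of 15 cases and rose in 3, on either adjustment (adjusted over the list alone, 7 and 3; camera adjusted p = 0.606), or 10 and 2 with library totals, and Lrat fell from 6.56 ± 0.943 to 2.13 ± 0.669 CPM. Heparin replicate 1 stood apart in these lists. Its median member lay at -1.95 for endothelium, -0.95 for Kupffer cells and -0.81 for stellate cells on the log2 scale against the control mean, where heparin replicates 2 and 3 lay at -0.05 and 0.28, -0.19 and 0.04, and -0.36 and -0.14. It was also the lowest for B cells (-3.23, against -1.92 and -1.06). Leaving out each library was set beforehand, while these lists were picked for it after seeing the data. Without heparin replicate 1, 6 endothelial markers rose and 2 fell, 3 Kupffer cell markers rose and 2 fell, and 3 stellate cell markers rose and 6 fell, while 8097 genes were called in all.

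**Figure D3:**
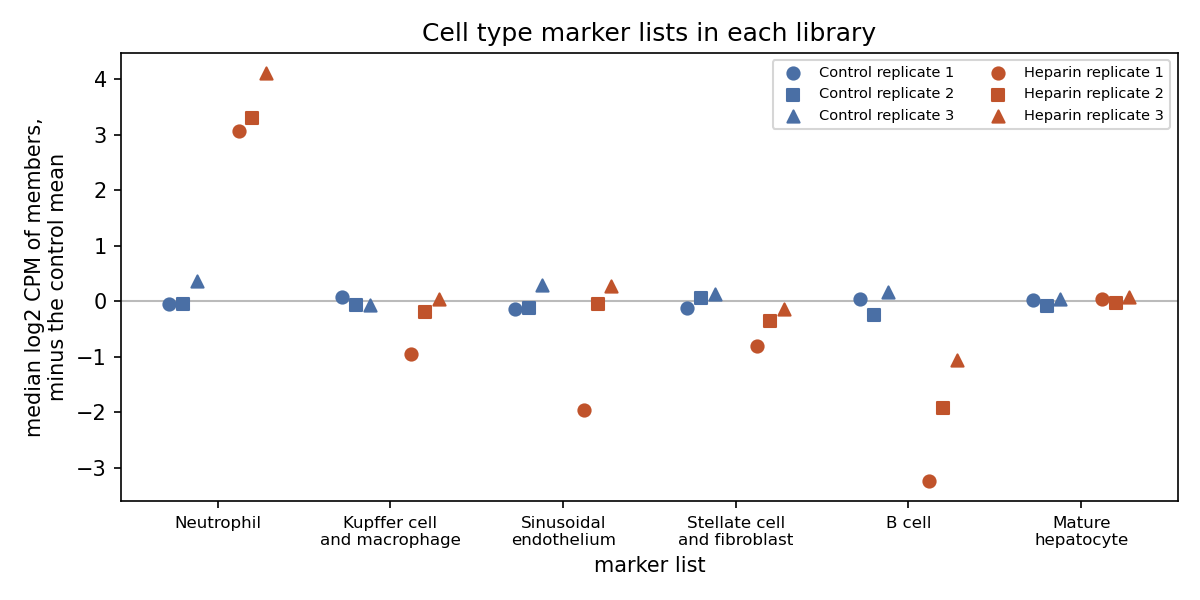
Median log2 CPM of the members of 6 cell type marker lists in each library, minus the mean of the control libraries (y axis); colours are the groups and symbols the replicates. The 3 heparin libraries lie at 3.07 to 4.10 for neutrophil markers, and heparin replicate 1 lies at -1.95 for sinusoidal endothelium.

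Platelet and megakaryocyte markers rose in 2 of 6 cases and fell in 1 on either adjustment (adjusted over the list alone, 2 and 1; camera adjusted p = 0.873), and the integrin gene Itgb3 rose from 1.35 ± 0.343 to 6.86 ± 3.15 CPM. Pf4, platelet factor 4, rose by 1.40, a call that ended with library totals and without control replicate 2 or heparin replicate 2 (adjusted p = 0.0758, 0.0688 and 0.0868, against 0.00724 to 0.0868 over its alternatives). Cholangiocyte markers rose in 3 of 9 cases and fell in 2, also when adjusted over the list alone (camera adjusted p = 0.606), and Sox9 rose from 2.63 ± 0.789 to 61.7 ± 5.83 CPM. Erythroid markers fell in 2 of 7 cases, Hba-a1 and Hba-a2, also when adjusted over the list alone (camera adjusted p = 0.823), while 5 fell with library totals. Reads can be shared between Hba-a1 and Hba-a2. Hba-a1 (log2 fold change -0.72) lost its call without control replicate 2 or 3, at -0.74 and -0.62 (adjusted p = 0.0826 and 0.0723, against 1.74e-08 to 0.0826 over its alternatives). Hba-a2 (-0.87) lost its call without control replicate 3, at -0.77 (adjusted p = 0.0559, against 5.43e-04 to 0.0559). Adipocyte markers, several of them also expressed in liver, fell in 4 of 5 cases, also when adjusted over the list alone (camera adjusted p = 0.142), with Lipe going from 13.2 ± 0.638 to 3.91 ± 0.282 CPM. Of 6 MHC class II genes 1 fell, Ciita, and none when adjusted over the list alone (camera adjusted p = 0.873). Without control replicate 2 or 3 or heparin replicate 3 the adjusted p of Ciita was 0.0777, 0.0747 and 0.0805, against 0.00693 to 0.0805 over its alternatives. Its log2 fold change was then -2.13, -2.17 and -1.66, against -2.22 with all libraries. Mitochondrially encoded mRNAs rose in 3 of 13 cases, also when adjusted over the list alone (camera adjusted p = 0.606), and 1 rose and 2 fell with library totals. Of 4 T and NK cell markers, too few for a list test, Cd4 fell from 4.86 ± 0.546 to 1.44 ± 0.329 CPM, the only call also when adjusted over the list alone. Cd3e, Ccl5 and Nkg7 were not called, at log2 fold changes of 1.63, 1.08 and 0.78. They had 17, 38 and 25 control counts, where Cd4 had 462. Cela1, the 1 exocrine pancreas gene tested, stood at 24.5 ± 3.27 and 21.4 ± 5.08 CPM and was not called. It was called lower with library totals (log2 fold change -0.62, adjusted p = 0.00337) and without heparin replicate 3 (-0.40, adjusted p = 0.0184), against 0.00337 to 0.681 over its alternatives.

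Some members went against their list, and those in this paragraph were chosen after their values were seen. Among immediate early genes Ccn1 fell by 2.57 and Ier2 by 0.54, and among interferon-response genes Cxcl10 fell by 2.20, Psmb9 by 0.44 and Ifit1 by 0.42. Of the p53 targets Plk2 fell by 2.05, Sesn1 by 0.98, Bbc3 by 0.70 and Ccng1 by 0.26. Hsd17b7 was the 1 cholesterol synthesis gene that rose (0.40), and Cyp7b1 the 1 male-biased gene (0.22), and library totals called neither of them higher. Hsd17b7 lost its call without control replicate 3, and Cyp7b1 without control replicate 1 or 2 or heparin replicate 2 or 3. Of the NRF2 targets Hmox1, heme oxygenase 1, rose by 5.20 and Osgin1 fell by 3.48.

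In 12 lists the median, the mean and the camera direction did not share a sign. FGF receptors and ERK cascade genes had a median of 0.15, a mean of -0.09 and a downward direction, and clock genes 0.15, -0.09 and downward. Coagulation factors had -0.06, 0.46 and upward, and complement -0.06, 0.10 and downward. The others were heparan sulfate genes, xenobiotic metabolism, NRF2 targets, heat shock genes, hepatocyte, Kupffer cell and endothelial markers and MHC class II. With library totals, members called were 11 up and 0 down for inflammatory genes, 15 and 1 for ER stress, 7 and 4 for p53 targets, 8 and 4 for gluconeogenesis and 7 and 0 for neutrophils. They were 0 and 6 for B cells, 1 and 3 for Kupffer cells, 1 and 2 for endothelium, 0 and 5 for adipocytes, 0 and 2 for MHC class II, 1 and 1 for platelets and 2 and 2 for cholangiocytes. With the preset correlation 10 lists were called for the real groups, and other splits of the 6 libraries into 3 and 3 called 6 to 13. Those splits mix control and heparin libraries on each side and keep part of the group difference, so their calls are not a chance level.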

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

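The call of Hrg kept its direction and stayed past the threshold in each alternative, from -0.63 to -0.69 on the log2 scale except for -1.10 with library totals. Leaving out each library gave 7380 to 8097 changed genes, 3725 to 4112 higher, 3612 to 3985 lower, -0.63 to -0.69 for Hrg and 10 to 12 lists. The other settings gave 8089 to 9062 changed genes. Library totals alone moved the median gene by -0.44, so that 24.1% of calls were higher (2183 higher, 6861 lower) in place of 50.4%. They kept 6329 of the 8250 calls in the same direction and turned 56. Under them Por was at -0.19, below 0 where TMM put it above. The shift follows from the construction of that setting, which lets genes taking more of the heparin counts lower the rest. Lists called numbered 4 with an estimated correlation and 24 with fry, which asks another question. Over all settings the named genes other than Hrg kept their call 2530 times, gained one 30 times, lost one 26 times and reversed 1 time, and lists kept theirs 593 times, gained 23 and lost 8. Deviations of same-numbered libraries had correlations of 0.003, 0.003 and 0.117, where differently numbered ones ran from -0.106 to 0.094. This gives no clear sign that the numbers pair libraries, but so few values cannot exclude it. The replicate block gave 8261 changed genes. Depth limits the lymphocyte, neutrophil and cell cycle markers, many of which lie near 1 CPM.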

Other observations

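The gene families and the clock genes named here beyond the lists' leading members were picked after their values were seen, as were the test of dilution for Hrg and the test of Ciart against Dbp and Per3. Families were tested as a set of 9 with camera. The adjusted p-values of the families do not allow for that choice and only describe these data. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, 18 rose and none fell (median log2 fold change 0.74, adjusted p = 1.76e-05; adjusted p = 0.0657 with an estimated correlation), and 11 rose and 3 fell with library totals. Yars rose by 1.77 and Wars by 1.62. Of 42 ribosome biogenesis factors 36 rose and 1 fell (median 0.81, adjusted p = 6.75e-06; adjusted p = 0.183 with an estimated correlation), and 23 rose and 6 fell with library totals. Nop58 rose by 2.41 and Rrp12 by 2.47. Ribosomal protein genes were not called as a family (adjusted p = 0.231), with 33 of 79 higher and 1 lower, which turned to 1 higher and 35 lower with library totals.

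Amino acid transporters rose in 12 of 23 cases and fell in 2 (adjusted p = 7.86e-04; adjusted p = 0.183 with an estimated correlation), and 10 rose and 6 fell with library totals. The neutral amino acid carrier Slc7a5 rose by 4.17, the cationic carrier Slc7a1 by 3.98 and Slc38a2 by 3.15. Replication-dependent histone genes went the other way, with 10 of 11 lower and none higher (median -1.36, adjusted p = 0.0168; adjusted p = 0.33 with an estimated correlation), and all 11 lower with library totals. Whether these counts came from polyadenylated transcripts or from other RNA carried through the enrichment was not tested. Among further families, oxidative phosphorylation genes rose in 11 of 72 cases and fell in 4, which turned to 0 and 41 with library totals. Proteasome subunits rose in 18 of 38 and fell in 2, which turned to 3 and 21. Zinc finger genes rose in 68 of 288 and fell in 74, or 30 and 130 with library totals, and Pex genes rose in 4 of 16 and fell in 6, or 0 and 12. None of these was called as a family, at adjusted p of 0.694, 0.297, 0.601 and 0.408.

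Fewer genes were detected with heparin, at 17610 to 17740 genes with a count against 18275 to 19013 in control libraries, although the heparin libraries were deeper. A few abundant genes do not account for it: without the 500 most abundant genes of each library and at 1 thinned total, the control mean stayed 953 genes higher, with every heparin library below every control library. Stray reads from silent loci do not either, since olfactory and vomeronasal receptor genes had a ratio of shares, control over heparin, of 1.05 with overlapping libraries. GC or length dependent loss stays open, as the correlation across genes of fold change with GC was -0.105, weak but past the bound of 0.1 set for excluding it, and genes are not independent replicates. Among genes tested, the median log2 fold change was -0.359 under 1 CPM and 0.158 over 100 CPM. By biotype it was -0.966 for antisense genes and -0.877 for long intergenic noncoding RNAs. For protein-coding genes it was 0.0124 and for processed pseudogenes 0.21. A lower number of weakly transcribed genes with heparin may also be part of the response, and that was not tested.

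Clock genes moved far, and livers taken at different times of day are a candidate explanation. Genes that peak in antiphase moved apart, with a median of 1.16 for Arntl, Clock and Npas2 and of -1.77 for Dbp, Nr1d1, Nr1d2, Per3, Ciart and Tef, as a shift of time would give. It does not account for Ciart, which rose by 3.56 while Dbp and Per3, with a similar time of peak, fell, a difference of 7.68. The labels give no time of day, and a response of the clock to inflammation, which the groups would also show, was not tested.

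Hrg stood at -0.66 after TMM scaling, past a bound of -0.58 that was set after its value was seen. It thus fell further than the bulk of genes, which TMM centres. With 59.2% of genes called changed, that scaling may not remove all of the dilution among induced transcripts, so the test cannot exclude dilution. For a general fall of plasma protein genes, the percentile test set beforehand did not decide. Hrg lay at percentile 7.27 of 55 other coagulation, anticoagulant and complement genes, and 4 fell further (Serpind1, Klkb1, Proz and Serpina5). After TMM scaling 22 of the 55 rose and 17 fell, with a median log2 fold change of -0.04, which argues against a general fall under that scaling. With library totals more genes fell than rose in each of these lists, so the explanation stays open there. An effect of heparin on Hrg through the receptors or ERK was not tested by these data.

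The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixes control and heparin libraries on each side. The wide difference between the groups then counts as spread within a side, which by itself leaves few genes to call. The gene counts of those splits are therefore not a chance level, and no conclusion is drawn from them. The real split called 8250 genes, 4160 higher and 4090 lower, and the highest of the other splits 0 in each case with edgeR, so that 1 of 10 gave as many. At an unadjusted p under 0.05 the real split had 8772 genes and the others 42 to 144, and DESeq2 called 8089 and 0 to 3. For lists the real split called 10 and another split 13, and 6 of 10 splits gave 10 or more. The sides of the mixed splits still differ in how many heparin libraries they hold. Their list calls thus keep part of the group difference and are not a chance level either.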
